A study of Mus musculus with 4 samples.

How the data were processed

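RNA from mouse embryos was measured on 4 Affymetrix Mouse Gene 2.0 ST arrays, 1 each for wild-type head and Tbx1 knockout head at E12.5 and for wild-type and Tbx1 knockout palatal shelves at E13.5. Per the labels' protocols, dissected tissue was frozen in liquid nitrogen, total RNA was extracted with TRIzol and a column kit, and 100 ng was labelled with biotin. The deposited values are log2 expression per transcript cluster, made by the authors with Affymetrix Expression Console and RMA, per the submitters' processing notes. Versions, the genome build and the annotation used are not given in the sources used here. RMA corrects background, sets the arrays to 1 common distribution and summarises probes, so a shift shared by most genes would be removed and folds of dim genes are compressed. The values ran from 1.63 to 13.55 with nearly equal quartiles on the arrays. No array pair held identical values. Arrays carry no read depth, and their number limits the precision.

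Groups were taken from the sample titles. In 1 other field of the labels the E13.5 samples are also called heads, whereas title, source and tissue name palatal shelves. The titles were followed, and the comparison of the shelves with the head bears on this choice, although the stage differs too. The labels give no replicate numbers and do not say whether RNA of several embryos was pooled. Residual spread and p-values therefore describe these arrays.

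Transcript clusters were named through the platform annotation. Of 41345 clusters, 23521 had 1 gene symbol, 1814 had several and 16010 had no listed gene, and clusters of the last 2 kinds were not used for named genes. By Entrez identifier, 23328 of the named clusters matched a RefSeq gene table of GRCm38.p6, used only for names, 193 kept the symbol of the annotation and 0 symbols changed. Clusters of 1 gene were averaged on the log2 scale, giving 22180 genes, of which 1082 had several clusters. Among genes with 2 bright clusters, the knockout minus wild-type differences of the 2 clusters were set against each other. Their disagreement, as an SD per cluster, was 0.176 in the head (232 genes) and 0.226 in the shelves (233 genes). It measures how far probe sets of 1 gene disagree. Over all genes that entered, the SD of the difference was 0.157 in the head and 0.259 in the shelves. Close relatives such as the actin, myosin and troponin genes can share probe signal, so levels of single members are less certain than those of the group.

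Choices in this paragraph were made before the data were examined. A gene entered a pair when the higher of its 2 arrays was at or above log2 6.16, the median over named genes and arrays. Within a pair, differences are knockout minus wild type, counted from 2-fold (log2 difference of 1), with no test. The genotype effect over both pairs and the difference between shelves and head came from 1 additive limma fit (lmFit and eBayes, Benjamini-Hochberg adjustment) of genotype and tissue, with 1 residual degree of freedom. Each of the 30 gene lists was summarised by its median difference, and the median was ranked among 10000 random lists of the same size matched on mean expression in 20 bins. A list stood apart below percentile 2.5 or above percentile 97.5, and a list with fewer than 3 members entering had no value. The text names Tbx1, the 10 genes with the largest difference each way per pair, genes at least 2-fold the same way in both pairs, up to 4 members per list and pair with the largest absolute difference, and up to 10 genes each way per coefficient of the fit. Predicted genes, olfactory and vomeronasal receptors and small RNAs were counted and skipped when naming. The text gives a selection of the genes so named. Some list members were not analysed here.

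Alternatives were centring each array on its median, quantile normalization again, cyclic loess, the brightest cluster of a gene, no filter or an upper-quartile filter (log2 7.79) on dim genes, and counts at 1.5-fold and 3-fold. The prior of the limma fit, estimated from all genes, had 5.49 degrees of freedom. For that fit the alternatives were a mean-variance trend, robust eBayes and 1 common variance. For the lists they were members bright in both arrays, the mean in place of the median and leaving out members shared between lists. After the data were seen, counts were added without the sex-linked list and without head-rich genes, 4 further gene lists were written, and the members passing over a list alone were counted under each setting of the fit.

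The additive fit was tested on simulated data for the genotype effect over 11999 genes, in 5 runs with 100 changed genes per size. It recovered 97.4% of genes changed by 1 on the log2 scale and 100% of those changed by 2, and 86 of 1073 calls were false, more than the 5% that the adjustment aims at. The planted changes were the same in both tissues, with noise drawn from the fitted prior. The shares recovered therefore do not hold for genes whose difference varied between the pairs, and they depend on how many changed genes were planted. The list step was tested on the shelves over 11449 genes with 1000 lists per size. It called 4.8% of unshifted lists of 10 genes and 5.0% of those of 30 genes apart, and 99.8% and 100% of lists shifted by 0.3. The differences were shuffled over genes for this test, so it does not cover lists whose members vary together. A first run of the list test with fewer lists was repeated with 1000 to narrow these shares. Calculations used R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.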

Results

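Gene expression was measured on 4 Affymetrix Mouse Gene 2.0 ST arrays, which read RNA along the exons of each annotated transcript. Tbx1 encodes a T-box transcription factor needed for development of the pharyngeal apparatus, and knockout embryos (mixed C57BL/6J and FVB/N background) were set against wild-type embryos. The arrays held 1 wild-type and 1 knockout sample of the head at embryonic day 12.5 (E12.5), and 1 wild-type and 1 knockout sample of the palatal shelves at E13.5, the outgrowths that form the secondary palate. The question was which genes differ without Tbx1 in the head and in the palatal shelves. Values are log2 expression (RMA), and a gene entered a pair when the higher of its 2 arrays reached 6.16, the median over all named genes and arrays. With 1 array per group, no difference within a pair has a replicate check, no p-value is given for it, and the number of arrays limits the precision. Pearson's r over all 41345 transcript clusters was 0.991 between the head arrays and 0.988 between the palatal shelf arrays, and lay between 0.973 and 0.979 across tissues.

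Tbx1 itself was lower in both knockout arrays. Its level in the head was 6.83 in wild type and 6.25 in the knockout, a 1.49-fold difference, and in the palatal shelves 7.39 in wild type and 6.18 in the knockout, a 2.32-fold difference. The knockout levels lay close to the limit for entry (6.16), where folds are compressed. Which part of the gene was deleted, and whether the probes lie in it, is not given in the sources used here, so the level may not test the genotype labels.

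In the E12.5 head, the knockout array had lower levels of an inner ear gene and of genes of differentiated skeletal muscle than the wild-type array. Oc90, which encodes the main matrix protein of otoconia in the inner ear, was 7.04-fold lower, with log2 levels of 8.77 in wild type and 5.95 in the knockout. Actc1, a sarcomeric actin made in heart and in embryonic skeletal muscle, was 2.15-fold lower (9.66 in wild type and 8.55 in the knockout). Mylpf, the regulatory light chain of fast skeletal myosin, was 2.14-fold lower, and Casq2, a calcium-binding protein of the sarcoplasmic reticulum, was 2.12-fold lower. H2bc9, a histone gene, had a log2 difference of -1.07 and Xist, the noncoding RNA of the inactive X chromosome, one of -1.06. These 6 genes were the ones at least 2-fold lower among 11364 genes that entered.

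The 4 genes at least 2-fold higher in the knockout head were 3 genes of the Y chromosome and 1 long noncoding RNA. Eif2s3y was 2.66-fold higher, Uty 2.62-fold and Kdm5d 2.49-fold, and the noncoding RNA Dubr was 2.16-fold higher. Xist was read in every array, from 10.04 in the knockout head to 11.10 in the wild-type head, and Eif2s3y ranged from 7.09 in the wild-type head to 8.50 in the knockout head. Sex-linked levels thus differed along with genotype in the head, beside the muscle and inner ear genes, and whether several embryos were pooled is not stated. Without the sex-linked list, 1 gene was higher and 5 were lower. Next in order among the lower genes were Myh3, the embryonic myosin heavy chain (log2 difference -0.93), Mymk, the fusogen of myoblasts (-0.89), AI506816 (-0.88) and Neb, the giant thin-filament protein nebulin (-0.87). Next among the higher genes were Rpl22l1 (0.73), the hyaluronan-binding gene Cemip (0.71), Zfp366 (0.65), Cdc42ep2 (0.64), Eomes, a T-box factor of cortical progenitors (0.58), and the clock gene Ciart (0.58).

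As a group, the skeletal muscle contractile genes stood apart in the head. Their median log2 difference was -0.45, below all 10000 random lists of matched expression, 23 of 24 members were below 0 and 3 were at least 2-fold lower. The myogenic regulators had a median of -0.092 (percentile 3.05), inside the range of random lists, but lay below that range under 5 of 7 alternatives, with values from -0.22 to -0.013 over all of them. Of its members, Myf5 (-0.64) and Myod1 (-0.54), which commit cells to the muscle lineage, were lower. The inner ear list had a median of -0.25 over 8 members, with Pax8 at -0.86 and Pax2, a factor of the otic vesicle, at -0.43, while Lmx1a was at 0.52. Genes of the pharyngeal pouches and neck glands had a median of -0.31 over 6 members, which include Tbx1 and Pax8. The erythroid list had a median of -0.31 with 9 of 9 members below 0, among them Kel (-0.80), the embryonic globin Hbb-bh1 (-0.56) and the anion exchanger Slc4a1 (-0.45). Proliferation genes had a median of -0.10 with 20 of 23 below 0, and genes of Schwann cells, neural crest and melanocytes a median of -0.13 over 9 members, with the pigment gene Pmel at -0.49.

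Few groups were higher in the knockout head. The endothelial list had a median of 0.095 with 13 of 18 members above 0, led by Egfl7 (0.37), and the hypoxia and glycolysis list a median of 0.092 with Vegfa, the main endothelial growth factor, at 0.36. The sex-linked list had a median of 1.35. The inner ear list came inside the range of random lists with members bright in both arrays, the pharyngeal list did so without members shared between lists, and the Schwann cell list did so both without shared members and with the brightest cluster of a gene. The other 20 lists lay inside the range of random lists. Those tied to the face and palate had medians of -0.013 (palatal shelf patterning), 0.0515 (oral epithelium and periderm), -0.075 (osteoblast and bone matrix), -0.092 (cartilage), -0.10 (tooth germ), -0.032 (reported Tbx1 pathway genes) and -0.013 (retinoic acid). Of these, tooth germ (percentile 2.76) and cartilage (percentile 3.005) lay near the limit, and each came outside the range under 2 alternatives. Oral epithelium (percentile 96.26) and palatal shelf patterning each did so under 1. The miR-200 and ZEB list, which comes from published work of the same group and may have been chosen on these samples, had a median of -0.059 and is not independent evidence. Medians were 0.0087 for neurons, -0.036 for neural progenitors, 0.071 for eye and lens, -0.0079 for pituitary and olfactory epithelium, -0.034 for lymphatic endothelium, -0.11 for macrophages and other leukocytes and 0.0725 for smooth muscle and pericytes. The remaining medians were -0.079 for immediate early and heat shock genes, -0.082 for p53 targets, -0.15 for Hox genes, -0.062 for chromosomal neighbours of Tbx1 and -0.020 for cytosolic ribosomal proteins.

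In the E13.5 palatal shelves, the knockout array had lower levels of skeletal muscle genes, and higher levels of neuronal and of hypoxia-responsive genes, than the wild-type array. Among 11449 genes that entered, 53 were at least 2-fold higher and 54 at least 2-fold lower. Cyp2g1, a cytochrome P450 of olfactory mucosa, had a log2 difference of -4.17 (9.56 in wild type and 5.39 in the knockout), and Bpifa1, a secreted protein of the upper airway epithelium, was 5.70-fold lower (9.17 and 6.66). Fmo6, a flavin monooxygenase, was 6.64-fold lower, Mmp13, a collagenase of bone and cartilage, 5.14-fold lower, and Acsm4, an acyl-CoA synthetase of olfactory epithelium, 4.99-fold lower. The muscle gene Actn2, the Z-disc protein alpha-actinin-2, was 3.27-fold lower. The 10 most lower genes also included Sult1e1, the estrogen sulfotransferase (log2 difference -2.21), Atp8b4 (-2.14), S100z (-1.91) and Lrrc32 (-1.73).

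Of the 53 genes at least 2-fold higher in the knockout shelves, 3 are on the neuron list and 3 on the hypoxia and glycolysis list. Tmem130 was 6.50-fold higher (5.93 in wild type and 8.63 in the knockout), and the paternally expressed noncoding RNA Ipw 5.11-fold higher. Sfta3-ps was 4.31-fold higher, the imprinted gene Usp29 3.80-fold and the glycine receptor subunit Glra2 3.71-fold. Also among the 10 most higher were Zic1, a factor of the neural tube (log2 difference 1.79), Fam155a (1.78), the synaptic adhesion gene Nrxn3 (1.64), the calcitonin receptor gene Calcr (1.63) and Rit2 (1.59). The predicted gene Gm26504 had the highest difference of all genes that entered (levels of 7.06 in wild type and 10.06 in the knockout), and it is named here after its values were seen, because the naming rule left out predicted genes. Other transcript clusters carry its name together with small nucleolar RNA genes, so its level is uncertain. In the wild-type head, Tmem130 was at 9.07, Glra2 at 8.35 and Zic1 at 10.38. Of the 53 higher genes, 23 were at least 4-fold higher in the wild-type head than in the mean of both shelf arrays, and leaving out such genes left 30 higher and 54 lower. Leaving out genes at least 4-fold higher in the wild-type head than in the wild-type shelf array left 14 higher and 54 lower. Both definitions use arrays of the difference itself.

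Skeletal muscle genes were lower together in the knockout shelves. The contractile list had a median of -0.84, with 18 of 18 members below 0 and 8 at least 2-fold lower, including Actc1 (-1.68), Neb (-1.45) and Mylpf (-1.37). Myogenic regulators had a median of -0.14, with Myog, a factor of muscle differentiation, at -1.34 and Mymk at -1.29, while 4 of 12 members were above 0. The median of this list turned to 0.015 when only members bright in both arrays were kept, which leaves out members that fell below the limit for entry in the knockout. The sex-linked list had a median of 0.020, inside the range of random lists.

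The hypoxia and glycolysis list had the highest median among lists with a value in the shelves, 0.80, with 15 of 15 members above 0. Bnip3, a mitophagy receptor induced by low oxygen, was at 1.38, Vegfa at 1.17, the oxygen sensor Egln3 at 1.04, and the level of the collagen prolyl hydroxylase gene P4ha2 was 7.10 in wild type and 8.09 in the knockout. Neuronal genes had a median of 0.58 with 17 of 20 above 0, including Ina, an intermediate filament gene of neurons (2.78-fold higher), the neurofilament gene Nefl (log2 difference 0.95), the GABA-synthesising enzyme gene Gad2 (1.11) and the synaptic vesicle gene Syt1 (1.09). Neural progenitor genes had a median of -0.21 and went both ways, with Sox1 at 1.15, and the forebrain and midbrain factors Emx2 at -1.19, Olig2 at -0.90 and Otx2 at -0.88. The pituitary and olfactory list had a median of -0.21 and also held opposite members, Gng8, a G protein subunit of olfactory neurons, at -1.22 and Six6, a hypothalamic and eye factor, at 1.17.

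Palatal shelf patterning genes had a median of 0.14 with 27 of 35 above 0, such as Foxf1 (0.47), Fgf10 (0.43) and Shox2 (0.36), while Alx1, a factor of frontonasal mesenchyme, was at -0.44. Tooth germ genes had a median of 0.30, with Lef1 at 0.63, Foxi3 at 0.54 and Dlx2 at 0.53, and reported Tbx1 pathway genes a median of 0.17, with Isl1 at 0.58. The oral epithelium list had a median of -0.10 with 19 of 29 below 0, from Epcam at -0.42 to Krt15 at 0.57. Endothelial genes had a median of 0.22 with 15 of 16 above 0, the VEGF receptor genes Flt1 (0.63) and Kdr (0.49) among them. Macrophage and leukocyte genes had a median of -0.28, with Fcer1g at -0.76 and the mannose receptor gene Mrc1 at -0.73, and proliferation genes a median of -0.11 with 18 of 23 below 0. The smooth muscle and pericyte list had a median of 0.16 and went both ways, with Cspg4 at 0.68 and Acta2 at -0.90. The inner ear list had a median of 0.36 over 4 members. With the mean in place of the median, the oral epithelium, inner ear, smooth muscle and pituitary and olfactory lists came inside the range of random lists, and the last did so too without members shared between lists, with a median of -0.021.

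The other 14 lists with a value in the shelves, the sex-linked list among them, lay inside the range of random lists. Medians were 0.085 for osteoblast and bone matrix, -0.012 for cartilage, 0.097 for retinoic acid, 0.068 for the miR-200 and ZEB list, -0.027 for pharyngeal pouch and neck glands, -0.058 for Schwann cells, neural crest and melanocytes and -0.15 for eye and lens. They were -0.00050 for lymphatic endothelium, -0.068 for the erythroid list, 0.081 for immediate early and heat shock genes, -0.061 for p53 targets, -0.054 for chromosomal neighbours of Tbx1 and 0.057 for cytosolic ribosomal proteins. Hox genes had fewer than 3 members that entered. Of all list values, 9 of the head, 15 of the shelves and 12 of the mean of both pairs lay outside the range of random lists, out of 87, and by construction 5% of random lists do. The values of the mean are made from those of the pairs. Random lists are drawn without regard to function, whereas members of a gene list can vary together. The 5% is therefore no measure of how many gene lists would lie outside without an effect of genotype.

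**Figure D1:**
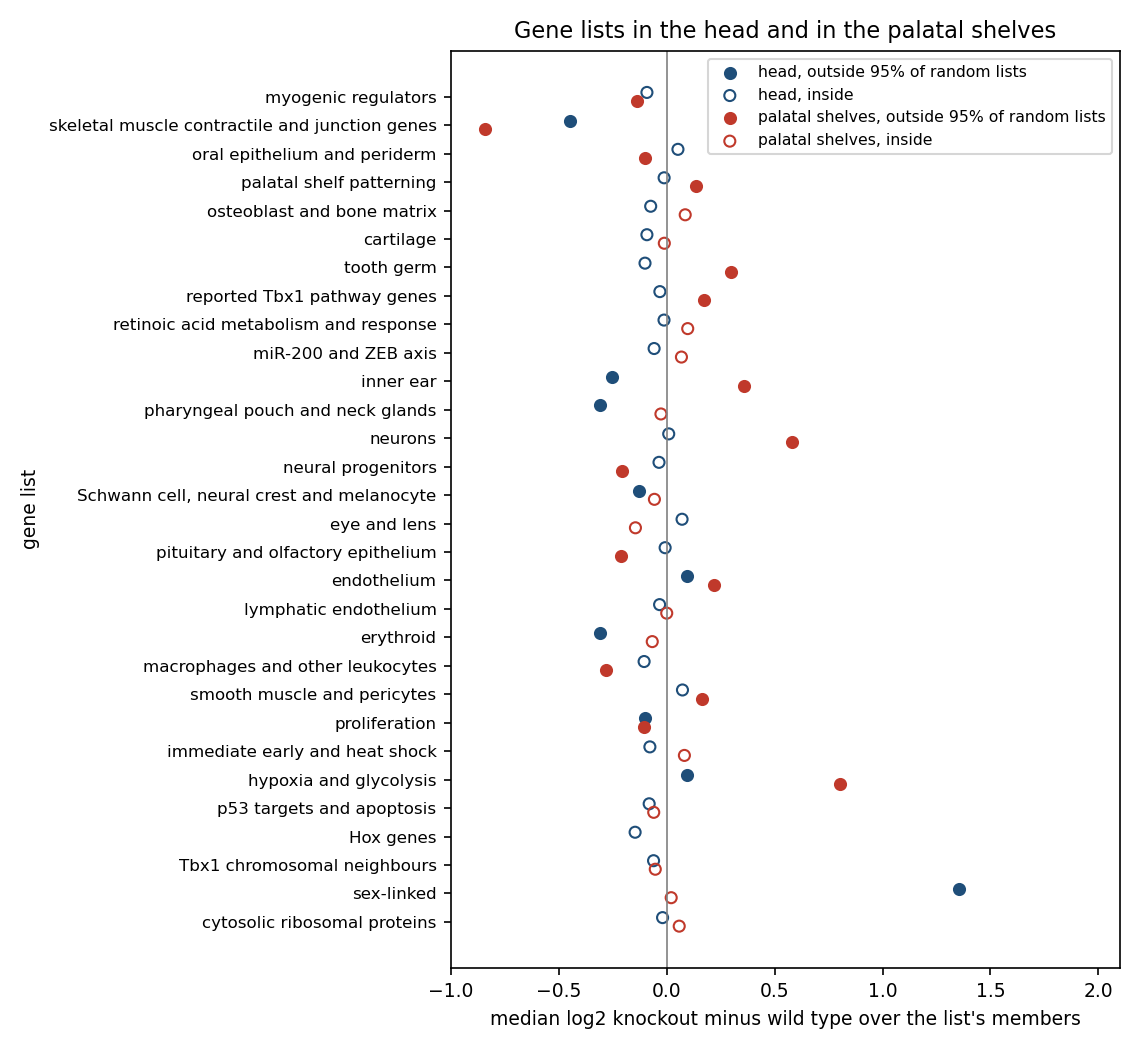
Median log2 knockout minus wild-type difference of each gene list (horizontal axis) in the E12.5 head (blue) and the E13.5 palatal shelves (red), 1 array per group. Filled points lie outside the central 95% of random lists of matched expression, such as skeletal muscle genes at -0.45 in the head and -0.84 in the shelves.

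The genes at least 2-fold lower in both pairs were muscle genes. Actc1 and Mylpf were at least 2-fold lower in the knockout of both head and palatal shelves, 2 genes where independent lists would share 0.0096, and no gene was at least 2-fold higher in both or opposite in the pairs. At 1.5-fold, 12 genes were lower in both pairs, of which 10 are on a muscle list, among them Ttn, the giant sarcomere protein titin, Tnnt2, a troponin T, and Myl1, a myosin light chain. Dubr was the 1 gene at least 1.5-fold higher in both. Across the 10814 genes that entered both pairs, the differences had a Pearson's r of 0.105 and a Spearman's rho of 0.066, and r was 0.0713 without the muscle lists. These correlations are across genes, which are not independent replicates.

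**Figure D2:**
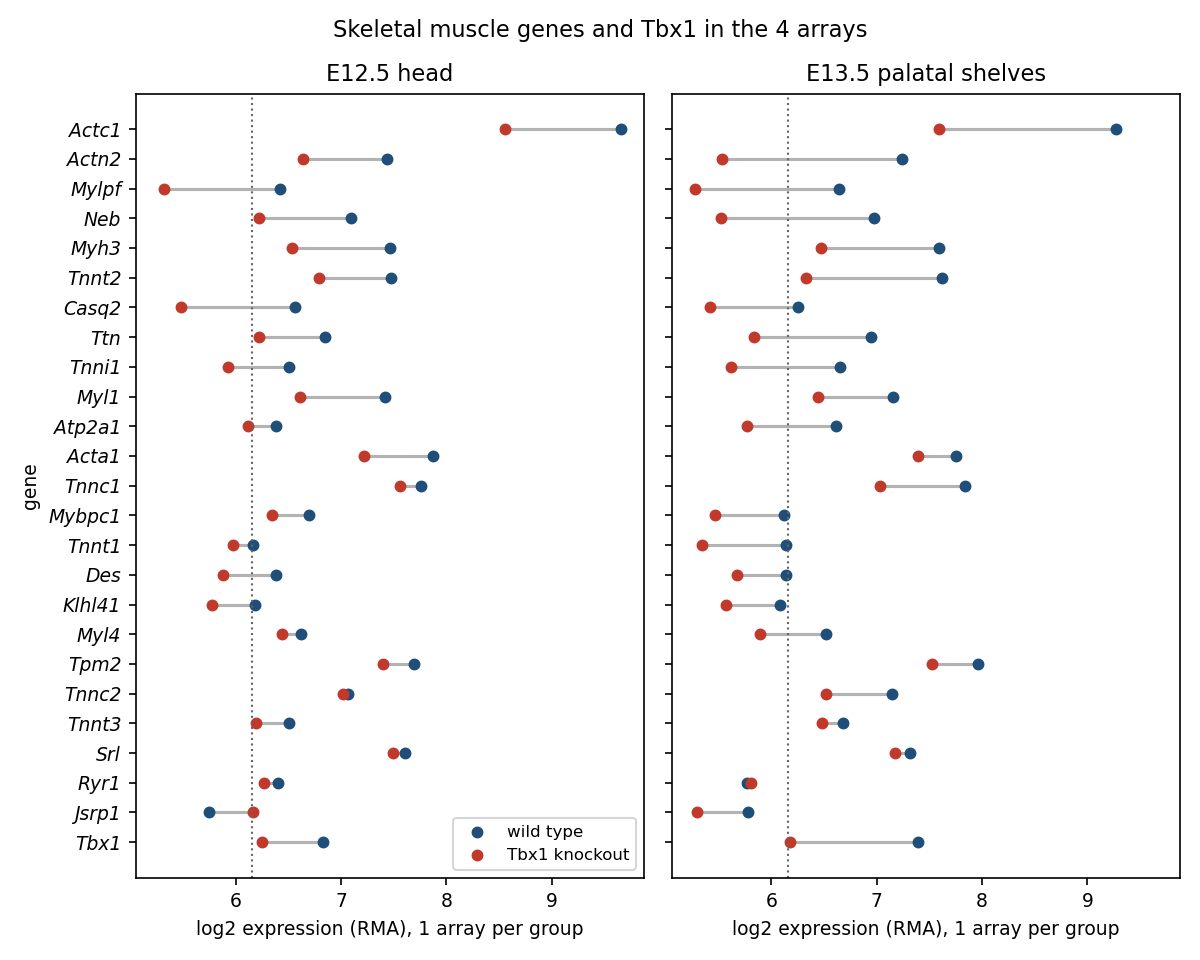
Log2 expression (horizontal axis) of skeletal muscle genes and Tbx1 in wild-type (blue) and knockout (red) arrays of the head and the palatal shelves, 1 array per group, with a dotted line at the limit for entry (6.16). Knockout points lie left of wild type for 23 of 24 muscle genes in the head, and for Tbx1 in both tissues.

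**Figure D3:**
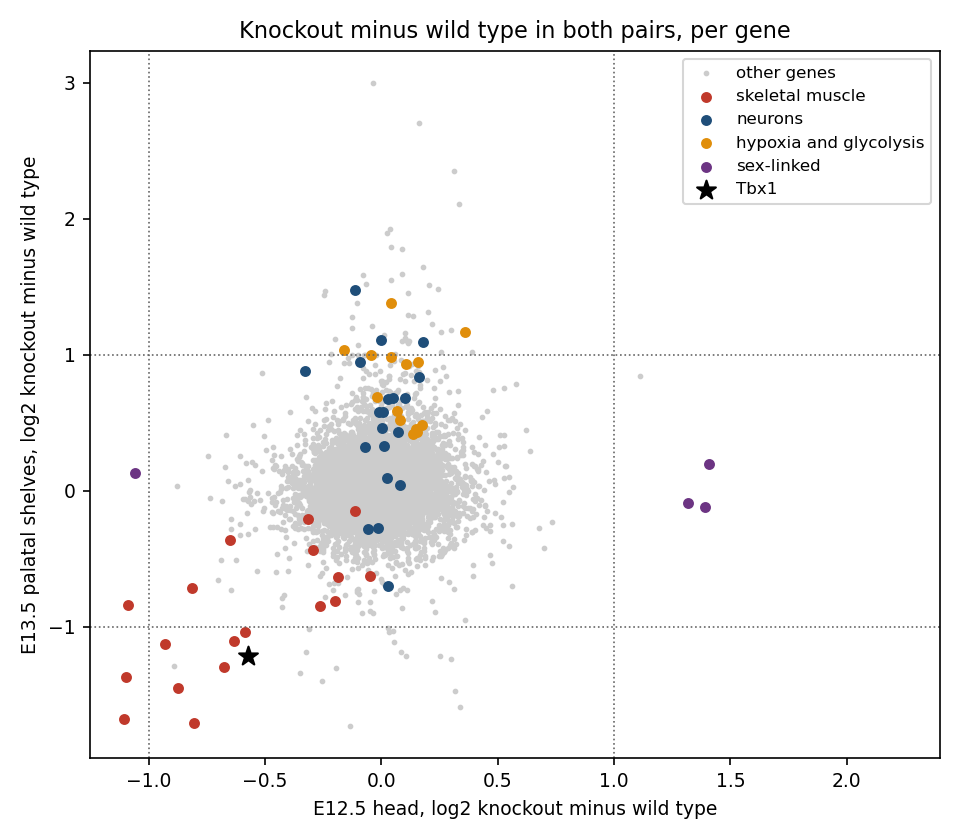
Log2 knockout minus wild-type difference in the head (horizontal axis) against that in the palatal shelves (vertical axis) for the 10814 genes that entered both pairs, with dotted lines at 2-fold. Muscle genes lie toward the lower left, neuronal and hypoxia genes are spread along the shelf axis, and 3 Y-linked genes lie at the right.

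Over both pairs, 5 of the 6 genes with the smallest adjusted p for genotype are on a muscle list, and the other was Dubr. The additive limma fit compared 2 knockout with 2 wild-type arrays with tissue as a block. A gene's spread joins how much its difference varied between the pairs (1 residual degree of freedom) with a prior from all genes (5.49 degrees of freedom, SD 0.107), so for genes with close differences in the pairs the SE and p rest mostly on that prior. Mylpf had a log2 difference of -1.23 (SE 0.11), Actc1 of -1.39 (SE 0.15), Myh3 of -1.03 (SE 0.11), Casq2 of -0.96 (SE 0.11), Mymk of -1.09 (SE 0.13) and Dubr of 0.98 (SE 0.11), each with a limma adjusted p of 0.172. The smallest limma adjusted p of any gene was 0.453 with each array centred on its median, 0.889 with cyclic loess and 0.925 with quantile normalization again. No gene of 11999 passed an adjusted p of 0.05, and 628 (5.23%) had an unadjusted limma p under 0.05, where 5% would with no effect on any gene. Under the same 3 alternatives 517 (4.31%), 573 (4.78%) and 560 (4.66%) did. With a mean-variance trend in limma's prior, 11 genes passed, 1 higher and 10 lower, and with 1 common variance 150 passed, 82 higher and 68 lower. For Tbx1 the difference was -0.89 (SE 0.16) with a limma adjusted p of 0.555 over all genes tested.

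Within the lists fixed beforehand, most contractile muscle genes passed when the adjustment covered their own list alone. That adjustment was made inside each list, with no further adjustment across lists. Members of a list were read on the same arrays and can vary together. The number passing is therefore no count of independent results, and a shared difference in muscle content would move many members at once. Adjusted over the list alone, 20 of 24 contractile genes fell in the knockout, against 0 adjusted over all genes tested, and 4 did not pass. Under recentring 20 of 23 did so, and 21 of 25 under quantile normalization and under cyclic loess. With the brightest cluster of a gene 18 of 21 contractile genes did so. The share was lower with no filter on dim genes, 24 of 44, and with the upper-quartile filter 4 of 4 did so. Mylpf fell by 1.23 on the log2 scale, Neb fell by 1.16 and Ttn fell by 0.87. Adjusted over the list alone, 4 of 14 myogenic regulators fell, namely Mymk, Myod1 (-0.56), Myog (-0.84) and Myf5 (-0.45), and 2 did so under quantile normalization and under cyclic loess. With no filter on dim genes 2 of 20 did so, and with the upper-quartile filter 0 of 7. In the hypoxia list 2 of 15 members rose when adjusted over the list alone, Ndrg1 (0.62) and Vegfa (0.76), but 0 did under recentring, quantile normalization, cyclic loess or the brightest cluster of a gene, and 15 with a mean-variance trend. Tbx1 fell as 1 of 7 members of the pharyngeal list. In the smooth muscle and pericyte list the pericyte gene Rgs5 rose (0.46) and Des, the muscle intermediate filament desmin, fell (-0.48), and in the retinoic acid list Rxrg fell (-0.46), where 0 members passed under recentring, quantile normalization or cyclic loess. No member of the other 24 lists passed in this way, whereas 6 of 26 neuronal genes rose with a mean-variance trend and 8 with 1 common variance. Other lists gained members too. Of 4 sex-linked genes, 3 rose and 1 fell under each of these settings, and of 15 neural progenitor genes 1 rose and 5 fell with the trend. With the upper-quartile filter, 1 of 3 inner ear genes rose and 2 fell, and 2 of 2 macrophage and leukocyte genes fell. Medians of the mean difference over both pairs lay outside the range of random lists for contractile genes (-0.79) and myogenic regulators (-0.16). They did so for pharyngeal genes (-0.18 over 4 members, Tbx1 itself among them) and for pituitary and olfactory genes (-0.16). The same held for erythroid genes (-0.15), macrophages and other leukocytes (-0.15) and proliferation (-0.088). Medians lay outside the range on the higher side for hypoxia (0.39), neurons (0.28), endothelium (0.18), smooth muscle and pericytes (0.12) and sex-linked genes (0.62). Several of these means rest mostly on 1 pair. Neurons had medians of 0.0087 in the head and 0.58 in the shelves, sex-linked genes 1.35 and 0.020, and hypoxia genes 0.092 and 0.80. On the lower side, erythroid genes had -0.31 in the head and -0.068 in the shelves, and pituitary and olfactory genes -0.0079 and -0.21. The myogenic list came inside the range with members bright in both arrays, the pituitary and smooth muscle lists did so with the mean, and the pituitary list also did so without members shared between lists.

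The palatal shelves differed widely from the head in the same fit, which is a limited check of the tissue labels. Bone and oral epithelial genes were higher in the shelves, with Ibsp, the bone sialoprotein gene, 80.8-fold higher (log2 6.34, SE 0.12, limma adjusted p 9.13e-06) and Panx3, a channel of osteoblasts and chondrocytes, 9.99-fold higher (SE 0.10 on the log2 scale, limma adjusted p 4.05e-05). Lens and brain genes were lower in the shelves, with Cryba1, a lens crystallin, at a log2 difference of -4.69 (SE 0.12, limma adjusted p 2.82e-05) and Neurod6, a factor of cortical neurons, at -3.40 (SE 0.13, limma adjusted p 4.27e-05). Of 11999 genes tested, 1555 were higher and 1787 lower at an adjusted p under 0.05. In the lists, 25 of 26 neuronal genes fell and 27 of 30 oral epithelial genes rose toward the shelves, over all genes tested and adjusted over the list alone. Of osteoblast genes 13 of 17 rose over all genes tested and 14 adjusted over the list alone, and of erythroid genes 7 of 9 fell by both counts. The shelves were taken 1 day later than the heads, so tissue and stage cannot be told apart in this comparison. The higher bone genes therefore do not by themselves check the tissue label of the E13.5 samples.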

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

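The inner ear list moved opposite ways in the pairs, with a median of 0.36 in the palatal shelves over 4 members (Cldn8, Pcdh15, Hmx2 and Otx1) and of -0.25 in the head over 8 members. The difference between the pairs was not tested, the members that entered are not the same in both, and the shelf value rests on few genes.

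Among transcript clusters with several genes or no listed gene, which the comparisons of named genes leave out, 96 of 5982 differed at least 2-fold in the head (32 higher and 64 lower in the knockout) and 134 of 6243 did so in the shelves (92 higher and 42 lower). In both pairs together 1 such cluster was at least 2-fold lower and 0 were higher. Among named genes 10 of 11364 differed at least 2-fold in the head and 107 of 11449 in the shelves. Clusters without a single named gene thus passed this size more often, above all in the head, and with 1 array per group their noise was not measured.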

How the results depend on the processing

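Counts at 2-fold stayed within 1.5 times under recentring, quantile normalization, cyclic loess and the brightest cluster of a gene, and Tbx1 moved by less than 1 SD of all genes. Of 396 values of named genes under these alternatives, 0 moved by 1 SD or changed sign from at least 2-fold. These values cover the most changed genes, genes named for both pairs or for the genotype effect, and named members of the contractile and hypoxia lists. Named members of other lists were not part of this check unless they were among those genes. Counts moved with the filter and the size, which change the number of genes that can count. In the head, higher genes numbered 10 with no filter, 2 with the upper-quartile filter, 12 at 1.5-fold, 0 at 3-fold and 1 without the sex-linked list, and lower genes 3 with the upper-quartile filter, 40 at 1.5-fold and 1 at 3-fold. In the shelves, higher genes numbered 18 with the upper-quartile filter, 219 at 1.5-fold and 12 at 3-fold, and lower genes 14, 153 and 13. Without genes at least 4-fold higher in the wild-type head than in the wild-type shelf array, 14 were higher. That definition was tried first and shares an array with the difference counted, so it was replaced, after its value was seen, by one against the mean of both shelf arrays, which left 30. The replacement uses both arrays of that difference. A gene higher in the knockout shelves raises the mean, so it is less readily counted as head-rich. All 3 exclusions were chosen after seeing the data.

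Genes lower in both pairs numbered 1 with the upper-quartile filter, 12 at 1.5-fold and 0 at 3-fold, and genes higher in both 1 at 1.5-fold. Pearson's r was 0.010 with no filter. The genotype effect had 11 genes with a mean-variance trend and 150 with 1 common variance, and 0 under every other alternative. Genes higher in the shelves than in the head numbered 1029 with the upper-quartile filter, where fewer genes were tested. Of 36 list values outside the range of random lists, 25 stayed outside under each alternative. Of their 252 values under alternatives, 13 came inside the range and 1 changed sign, myogenic regulators in the shelves at 0.015 with members bright in both arrays. That alternative leaves out members that fell below the limit for entry in the knockout, so it can move a lower list toward 0 by construction. Of the lists inside the range, 27 values came outside under an alternative. Replicates could not be paired because the labels give no replicate numbers and each group has 1 array, which also rules out leaving out replicates. Knockout and wild type were paired within a tissue only through the tissue block of the additive fit. Genes near log2 6.16 have compressed folds, which limits what can be read for dim genes, Tbx1 among them.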

Other observations

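The added gene lists and the tests of explanations in this part were chosen after the results were seen, while the oral epithelium, neural progenitor, myogenic regulator and immediate early and heat shock lists were fixed beforehand. Genes of the nasal lining were lower as a set in the knockout palatal shelves. A list of 44 nasal and olfactory genes, written after Cyp2g1 and Bpifa1 had been seen among the lowest, had a median log2 difference of -0.70 over the 23 members that entered, with 21 below 0 and 10 at least 2-fold lower. In the head its median was 0.059 over 13 members. Motile cilia genes, which the ciliated airway lining uses, had a median of -0.63 in the shelves with 15 of 16 below 0, and of -0.0088 in the head over 6 members. Genes of the hypothalamus and basal forebrain had a median of 0.42 in the shelves with 15 of 15 above 0, and of 0.00070 in the head over 16 members. Genes of cortex and hindbrain had a median of 0.080 in the head over 11 members and too few members that entered for a value in the shelves.

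Skeletal muscle genes were lower in both knockout samples. In the shelves a different sex make-up of the arrays is argued against by Kdm5d, Uty, Eif2s3y and Xist, which differed by at most 0.20 on the log2 scale, but in the head it stays open. Less muscle cut out with the knockout tissue also stays open. The myogenic regulators, several of which other cells make too, had a median of -0.14 in the shelves with 8 of 12 below 0. As a list they went both ways, which decides nothing. Mymk (-0.89 in the head and -1.29 in the shelves), Myog (-0.35 and -1.34) and Myod1 (-0.54 and -0.59) were lower in both pairs. In the shelves 4 of 12 members were above 0. With 1 array per group, less muscle in the sample cannot be told apart from an effect of genotype, which remains an untested hypothesis.

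The knockout shelves held higher neuronal and lower nasal genes, with the neuronal gene Syt1 at 7.16 in wild-type shelves, 8.26 in knockout shelves and 9.16 in the wild-type head. Brain tissue in the knockout sample may be the source, since 55 of 64 genes (85.9%) at least 4-fold higher in the wild-type head than in the mean of both shelf arrays were higher there, against 55.2% of all genes. The neural progenitor list had a median of -0.21 but went both ways, from Emx2 at -1.19 to Sox1 at 1.15 with 4 of 11 members above 0, which decides nothing, so the explanation stays open. A lower share of all epithelium would lower the oral epithelium list too, but its median was -0.10 against -0.70 for nasal genes. Less nasal tissue cut out with the shelves cannot be told apart from an effect of genotype with 1 array per group, and the nasal list without the 10 most lower genes still had a median of -0.60, with 17 of 19 below 0.

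Hypoxia and glycolysis genes were higher in the knockout shelves. Of the members of the list, 15 of 15 (100%) were higher there than in each of the other 3 arrays, by a median of 0.69, so a mixture with tissue like the E12.5 head arrays would not give these levels. Brain tissue of E13.5 was not analysed here, so brain tissue in the sample stays open. Stress during handling before freezing may be the source, but the immediate early and heat shock list lay at percentile 84.6 of random lists, which decides nothing. Handling and an effect of genotype also stay open, the latter untested.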
